A study of Mus musculus with 6 samples.

How the data were processed

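RNA was extracted with TRIzol from primary CAFs, checked on a Bioanalyzer (RIN of at least 9), selected for poly(A) and made into libraries with a TruSeq RNA kit, per the labels' protocols. Reads were processed with TopHat2 2.0.10 and HTSeq, with the mouse build mm9, per the submitters' processing notes. The authors deposited a table of raw counts per gene symbol, not normalised, with 24015 symbols and 6 columns of whole numbers. Whether counting used the strand, and how reads shared by similar genes were treated, is not given in the sources used here, so values of single members of gene families and of overlapping or antisense genes are uncertain. The columns write "sh" where the sample titles write "si", and each was matched to its sample by the group and number in its name. The table held 0 symbols of mitochondrially encoded genes and no rows for unassigned reads, and 0 per-sample columns were left unused. The reference annotation was of another build and served only for GC content and transcript length, with 98.4% of symbols matched. No coordinates are given.

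Total counts ranged from 12998168 to 18683852 per sample, so a count of 0 allows a level of up to 0.231 CPM in the shallowest library (3 counts of its total). Such limits cover counting error only. Groups were taken from the titles and the treatment labels, 3 control siRNA and 3 anti-Stat3 siRNA samples. The labels do not say that replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical within a pair. Between pairs it includes differences in level such as 10.96 to 1614 CPM for Lyz2 in the controls.

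Counts were tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16, with TMM scaling, filterByExpr (a minimum count of 10 and a total of 15, which left 13284 genes), the group as the only term and a Benjamini-Hochberg threshold of 0.05. Log2 CPM used a prior count of 2. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were alternatives. The gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 31 lists with 3 or more tested members. Lists were written before the data were examined, except the ribosomal protein genes, which were taken by symbol. With 3 samples per group an exact permutation test cannot give a two-sided p under 0.1, and with 3 pairs not under 0.25, so no such test was used.

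The sample titles number the replicates 1 to 3 in both groups. Deviations from the group means correlated at 0.83, 0.82 and 0.83 between samples of the same number and at -0.16 or below between all others, across genes, which are not independent. Deviations within a group sum to 0, so the negative values follow in part from the positive ones. Spearman correlations of the raw counts were 0.977 to 0.980 between a control and an anti-Stat3 sample of the same number. They were 0.958 to 0.967 between those of different numbers. The numbers were therefore taken to pair the samples, and fits with the replicate block are given beside those without. What a number shares (an animal, a culture or a day) is not given in the sources used here. The descriptions of the samples of pair 3 follow another naming scheme, which was tried as a batch term. That batch holds 1 sample per group, so its within-batch value is the change in pair 3.

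The rule for named genes, fixed before the data were examined, took Stat3, Il6, Stc1 and Mmp13, then the 10 called genes with the largest positive and the 10 with the largest negative change that had a mean log2 CPM of at least 1 and groups that did not overlap, and up to 4 members of each described list with the smallest p. In edgeR with the group alone 0 genes met the second part. It was therefore applied to the blocked DESeq2 fit, with the same direction in all 3 pairs in place of groups that do not overlap. This, the genes called by blocked edgeR, the other genes named only as called and the marker genes named by level were chosen after their values were seen. No member was named from lists with 0 calls in the blocked DESeq2 fit, apart from Lyz2. Of the genes the rule names, 1 is not reported here.

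The fits were tested on simulated data for the comparison of anti-Stat3 and control siRNA, 3 samples each, with 5 simulations of about 13141 genes and 200 changed genes in each. Of 500 genes changed 2-fold and 500 changed 4-fold, edgeR with the group alone recovered 0.2% and 35.6%, blocked edgeR 81.2% and 98.0%, blocked DESeq2 76.6% and 95.6%, and blocked limma-voom 80.2% and 98.0%. Among all calls, 9.86% were false in blocked edgeR, 9.75% in blocked DESeq2 and 9.36% in blocked limma-voom, above the nominal 5%, and 0 in edgeR with the group alone. Each simulated change had the same fold in all pairs, unlike many called genes of the data. Summed over the 5 simulations, blocked edgeR and blocked DESeq2 made similar numbers of calls, 994 and 954. In the data, which are 1 set, they made 8 and 220, so there the fits differed from each other. The totals themselves follow from the 200 changed genes per simulation and are not comparable with the data. The simulated rates may therefore not hold for the data. Alternatives were other scalings, tools and count filters, the batch term, each sample or both samples of pair 3 left out, a test against a 1.5-fold change and a threshold of 0.01. Blocked fits with other tools, scalings and filters, and without each pair, were added after the data were seen.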

Results

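Gene expression was measured by poly(A) RNA sequencing in primary cancer-associated fibroblasts (CAFs), the fibroblasts of the tumour stroma, grown out of mammary tumours of NeuT transgenic mice on a BalbC background. NeuT mice carry an activated rat Her2/neu transgene and develop mammary carcinomas. The cells received nanoparticles with control siRNA (3 samples) or anti-Stat3 siRNA (3 samples) at 1 ug/mL for 72 hours. The series compares these groups to find genes that depend on STAT3, a transcription factor activated by IL-6 family cytokines, in CAFs. Total counts were 14676958, 18683852 and 17493429 in control samples 1 to 3, and 16043022, 14455704 and 12998168 in anti-Stat3 samples 1 to 3. Samples with the same number deviated together from their group means, so each number is called a pair below. Levels are CPM, counts scaled to a common library total with TMM factors, and changes are log2 of anti-Stat3 over control siRNA.

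Stat3, the targeted gene, was lower in each anti-Stat3 sample than in each control sample. Its level was 328 ± 95.9 CPM with control siRNA and 65.2 ± 26.4 CPM with anti-Stat3 siRNA (SD, n = 3 each). By sample, the controls had 220, 359 and 405 CPM and the anti-Stat3 samples 34.7, 81.9 and 78.9 CPM. The mean of the 3 pair changes was -2.38 ± 0.27 (SD), which leaves 19.2% of the control level. The edgeR quasi-likelihood test with the group alone gave a log2 change of -2.33 ± 0.41 (SE), an unadjusted p of 9.8e-04 and an adjusted p of 1.00, so Stat3 did not pass. With the pair as a block it fell by 2.38 on the log2 scale in edgeR (SE 0.14, adjusted p = 0.0027), a call lost without pair 3 (adjusted p = 0.264), where blocked edgeR called 0 genes. In blocked DESeq2 Stat3 passed with each pair left out (adjusted p at most 1.2e-23).

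The transcripts of the secreted factors in the series title were lower after anti-Stat3 siRNA in each of the 3 pairs, from control levels that differed widely between pairs. Il6, a cytokine that itself activates STAT3, had 525, 29.4 and 26.0 CPM in the controls and 265, 13.7 and 8.98 CPM after anti-Stat3 siRNA. Its pair changes averaged -1.20 ± 0.28 (SD, n = 3). Stc1, the secreted glycoprotein stanniocalcin 1, changed by -1.72 ± 0.75 and Mmp13, a collagenase, by -1.71 ± 0.81 (SD, n = 3 pairs each). All 3 genes fell in DESeq2 with the pair as a block, with log2 changes of -1.18 ± 0.17 for Il6 (adjusted p = 1.5e-09), -1.70 ± 0.28 for Stc1 (7.1e-07) and -1.72 ± 0.32 for Mmp13 (6.6e-05; SE). None passed in edgeR with that block (adjusted p = 0.062, 0.14 and 0.16), nor in edgeR with the group alone, where the log2 changes were -1.01 ± 1.65, -1.25 ± 0.92 and -1.71 ± 0.93 (SE). Without control sample 1 the log2 changes in edgeR with the group alone were 1.78 for Il6, -0.52 for Stc1 and -0.84 for Mmp13, and without anti-Stat3 sample 1 they were -4.10, -2.90 and -1.88. Without anti-Stat3 sample 2 or 3 the Il6 change was -0.50 or -0.47, and without sample 3 the Stc1 change was -0.82. Each of these breaks a pair. With a whole pair left out, the 3 genes passed in blocked DESeq2 each time (adjusted p at most 2.9e-04 for Il6, 0.027 for Stc1 and 0.046 for Mmp13). In blocked edgeR all 3 passed without pair 1 (4.6e-04, 6.8e-06 and 0.019), Mmp13 alone without pair 2 (0.027) and none without pair 3. The 3 genes, which the study itself names, are not an independent list: their median was -1.25 with the group alone (camera adjusted p = 0.034, 4.7e-05 with the block, and adjusted p = 0.737 with an estimated correlation). That call was lost without control sample 1 (median -0.52, adjusted p = 0.424) and without anti-Stat3 sample 2 (-0.86, 0.216) or 3 (-0.82, 0.264).

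**Figure D1:**
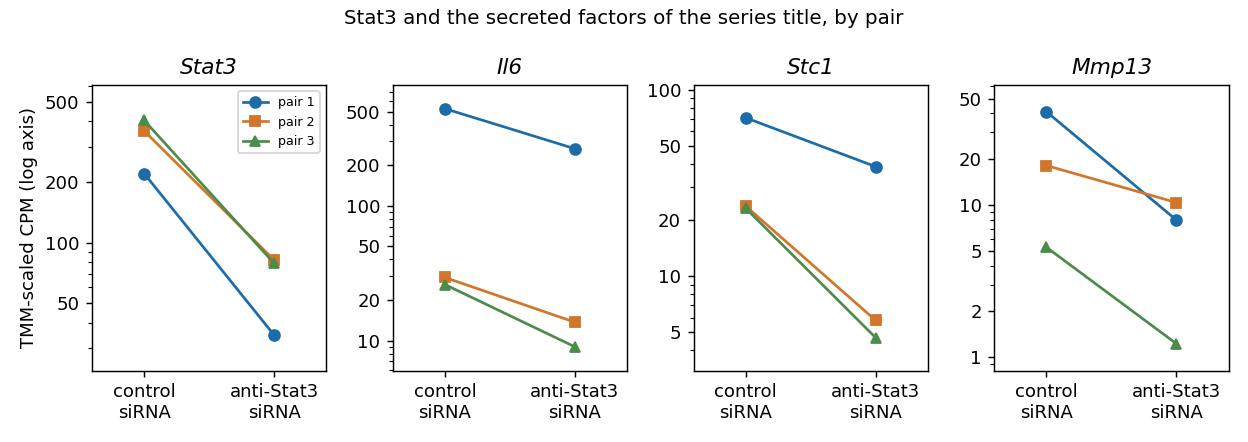
TMM-scaled CPM on a log axis of Stat3, Il6, Stc1 and Mmp13 in each library, with lines joining the control and anti-Stat3 sample of a pair. All 12 lines go down, and the Il6 control levels range from 26.0 to 525 CPM.

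Across all 13284 genes tested, the number past an adjusted p of 0.05 depended on the fit. The edgeR test with the group alone called 0 genes. It had 235 genes at an unadjusted p under 0.05, fewer than the 664 that chance would give. DESeq2 with the group alone called 17, of which 16 were higher and 1, Stat3, was lower. With the pair as a block, edgeR had 1439 genes at an unadjusted p under 0.05 and called 8 genes. Higher were Serpina3f, a serine protease inhibitor, Itgbl1, an integrin-like secreted protein, and Spry1, an inhibitor of receptor tyrosine kinase signalling. Lower were Stat3, Serpinb2 (plasminogen activator inhibitor 2), Socs3 (a feedback inhibitor of STAT3 signalling) and the metallothioneins Mt1 and Mt2. DESeq2 with the block, a fit chosen after the data were seen, called 220 genes, 116 higher and 104 lower, and all 8 genes of the blocked edgeR test were among them. Of the 220 genes, 218 moved the same way in all 3 pairs, which a blocked fit selects for. Among all tested genes 33.7% moved the same way in all 3 pairs, where chance gives 25%. The groups did not overlap for 83 of the 220 genes. Over all tested genes they did not overlap for 621, or 4.67%. Chance gives 10% for 6 samples without pairs, and less where pairs differ, so this share cannot be read as below chance. These counts rest on pairs 2 and 3. Without pair 1 the blocked edgeR test called 703 genes and DESeq2 called 432, without pair 2 they called 3 and 14, and without pair 3 they called 0 and 20.

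Among genes called in the blocked DESeq2 fit with a mean log2 CPM of at least 1 and the same direction in all 3 pairs, the largest falls were in Serpinb2, at -2.72 ± 0.24 (SE), Apln, the ligand of the apelin receptor, at -2.40 ± 0.49, and Stat3. Draxin, Xpnpep2, Kng2, Mmp3, Rtn4rl2, Socs3 and Ankrd55 followed, with log2 changes from -2.12 to -1.76. Several falls were small in pair 1, such as those of Ankrd55 (-0.06, -2.29 and -2.59) and Apln (-0.48, -2.93 and -3.23). Of the 104 genes called lower, 79 changed on average over 1.5 times as much in pairs 2 and 3 as in pair 1. So did 105 of the 116 called higher. The share among all tested genes was not computed, so these shares cannot be set against it. Serpinb2 was expressed mainly in pair 1, with 286 CPM in control sample 1 against 2.33 and 4.68 CPM in the other controls, yet its 3 pair changes were -2.65, -2.40 and -2.70. It had 0.34 and 0.61 CPM in anti-Stat3 samples 2 and 3, near the counting limit, so the size of its change in pairs 2 and 3 is uncertain. Socs3 fell from 89.0 ± 65.5 to 22.5 ± 14.0 CPM (SD, n = 3), a log2 change of -1.83 ± 0.21 (SE). Mt2 and Mt1, which bind metal ions, changed by -1.38 ± 0.16 and -1.11 ± 0.15. Itgbl1 rose by 2.03 ± 0.25, Serpina3f by 2.39 ± 0.37 and Spry1 by 1.03 ± 0.15 (SE). Under the same limits the 10 largest rises were in Gbp4, Gm4841, Cxcl9, Gm12250, Iigp1, Tgtp2, Gbp11, Gbp10, Cxcl10 and F830016B08Rik, most of them GTPases or chemokines known to be induced by interferon, with log2 changes from 4.14 to 8.63. Gbp4 had pair changes of 1.58, 9.50 and 10.34, from control levels of 5.95, 0.69 and 0.36 CPM. Gm4841 had 0.11 and 0.12 CPM in control samples 2 and 3, near the counting limit, while Iigp1 had 8.15 and 4.38 CPM. The size of a change from such low levels is uncertain: that of Gm4841 was 5.80 in blocked edgeR and 7.77 in blocked DESeq2. Guanylate-binding proteins, immunity-related GTPases and the Serpina3 genes belong to families of similar sequence, so the value of a single member is uncertain.

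**Figure D2:**
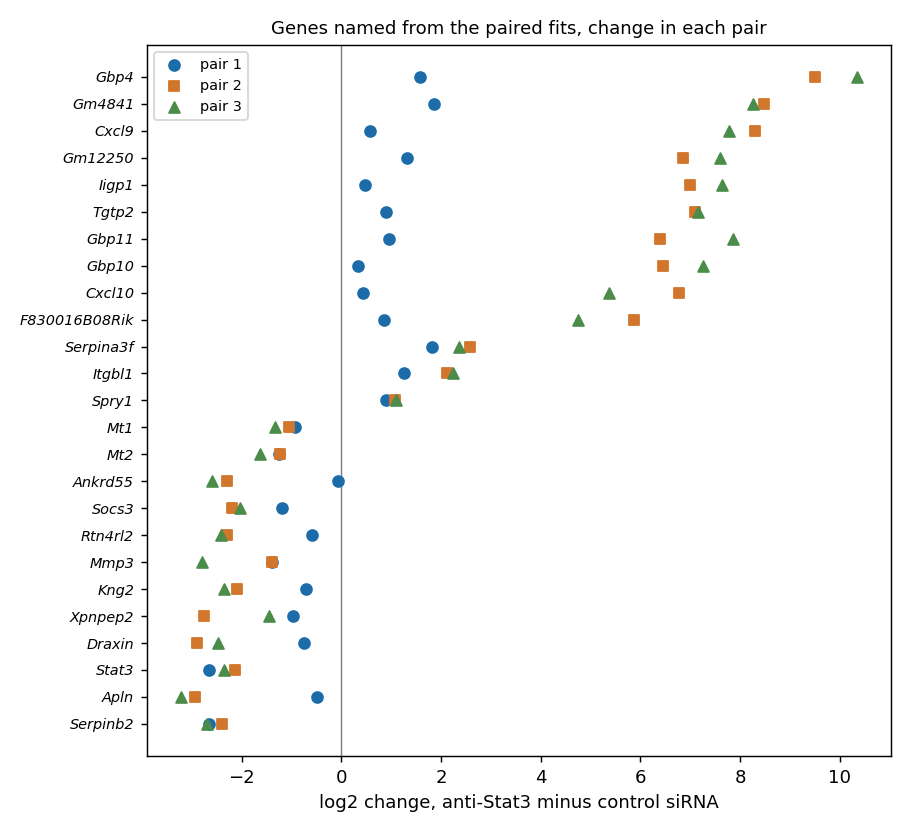
Log2 change (anti-Stat3 minus control siRNA) in each pair of the 25 genes named from the blocked fits. The 10 genes at the top moved by 0.33 to 1.85 in pair 1 and by 4.75 to 10.34 in pairs 2 and 3, while Stat3 and Serpinb2 lie close together in all pairs. Some genes that fell, such as Apln and Ankrd55, also moved least in pair 1.

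Genes known as STAT3 targets were lower as a group. The list, which holds Stat3 itself, had 31 of its 34 members tested, with a median log2 change of -0.40 in edgeR with the group alone and pair medians of -0.31, -0.54 and -0.48. In 18 members all 3 pairs were lower and in 3 all were higher, where 33.7% of all tested genes moved the same way in all pairs, in either direction. In the blocked DESeq2 fit 10 members fell and 1, Serpina3g (1.75 ± 0.35, SE), rose, and 20 did not pass. Besides Stat3 and Socs3, the members that fell include Hif1a, a subunit of the hypoxia-inducible factor, at -0.90 ± 0.20, Osmr, a receptor subunit for oncostatin M, at -0.85 ± 0.15, Bcl3 at -1.06 and Cebpd at -1.06. Adjusted over the list alone, 18 fell and 4 rose in that fit. In edgeR with the group alone, 0 members passed over all genes and 1, Stat3 itself, fell when adjusted over the list alone. The blocked edgeR test called 2 members lower over all genes, Stat3 and Socs3. Adjusted over the list alone it called 18 lower and 4 higher. Stat3 is the target of the siRNA, so its own fall says nothing about its targets, and the list was not tested without it. The camera test gave an adjusted p of 1.4e-04 (6.8e-06 with the block). With an estimated correlation, which was -0.018 for this list, the camera adjusted p was 0.239. The fry test gave an adjusted p of 0.052, and 0.137 with the block.

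Components of the JAK-STAT pathway showed no common direction, with 31 of 32 tested and a median of -0.04 (camera adjusted p = 0.830). In the blocked DESeq2 fit Socs3, Osmr and Jak3 fell and Socs1 rose. Adjusted over the list alone, 4 fell and 3 rose. Stat2, a component of the transcription factor complex of type I interferon signalling, had a log2 change of 1.47 ± 0.54 (SE) and did not pass over all genes (DESeq2 adjusted p = 0.18).

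Interferon-stimulated genes were higher after anti-Stat3 siRNA, by much more in pairs 2 and 3 than in pair 1. All 51 members were tested, and 49 were higher in all 3 pairs. The pair medians were 0.34, 2.82 and 2.90. The median member had 108, 19.7 and 19.2 CPM in the controls and 123, 155 and 131 CPM after anti-Stat3 siRNA, so that control sample 1 already lay near the anti-Stat3 samples. In the blocked DESeq2 fit 5 members rose over all genes and 49 when adjusted over the list alone. In blocked edgeR these counts were 0 and 51, and in edgeR with the group alone 0 and 0. Psmb9, a subunit of the immunoproteasome, rose by 3.41 ± 0.89 (SE) and Samhd1, a nuclease that restricts viral replication, by 1.33 ± 0.24. Tap1, a transporter of peptides for antigen presentation, and Irf1, a transcription factor of the interferon response, had changes of 2.38 ± 0.76 and 2.05 ± 0.72 that did not pass in that fit. The camera adjusted p was 5.4e-56 with the group alone, and 0.453 with an estimated correlation. With the block these were 3.4e-31 and 0.805.

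Macrophage markers followed the pairs and not the siRNA. The median of 19 tested markers was 0.27, 32.2 and 55.8 CPM in the controls and 0.56, 29.6 and 47.3 CPM in the anti-Stat3 samples. Lyz2, the macrophage lysozyme, had 10.96, 1208 and 1614 CPM in the controls and 11.7, 1198 and 1907 CPM after anti-Stat3 siRNA. The pairs with many macrophage transcripts were thus those with the large interferon-stimulated change. The list's pair medians were -0.05, 0.10 and 0.24 (camera adjusted p = 0.865), and 0 members passed in the blocked DESeq2 fit. Epithelial or tumour cell markers were highest in pair 2, where the median of 21 markers was 20.8 CPM with control and 20.2 CPM with anti-Stat3 siRNA. Their pair medians were -0.11, -0.06 and -0.01 (camera adjusted p = 0.729), and none passed in the blocked DESeq2 fit.

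**Figure D3:**
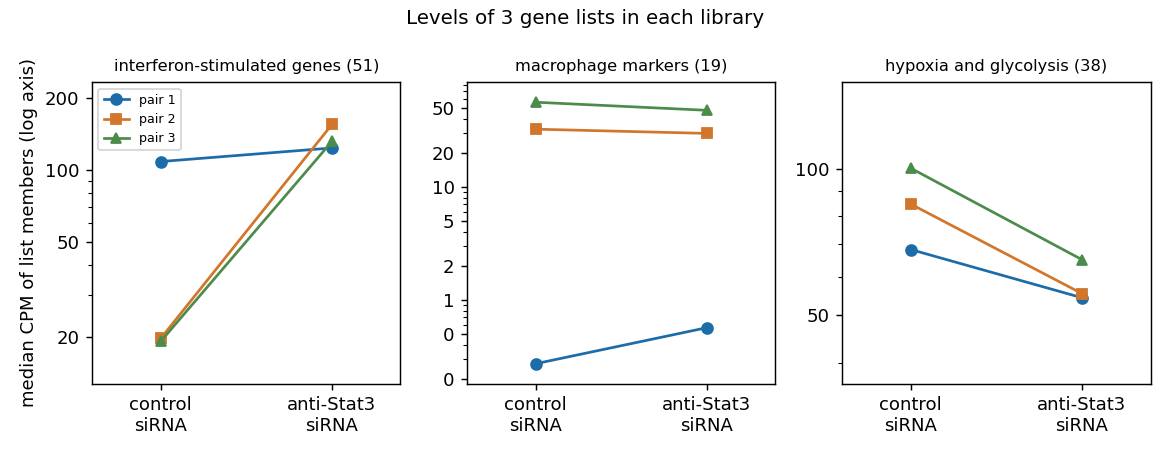
Median CPM over list members, on a log axis, of interferon-stimulated genes, macrophage markers and hypoxia and glycolysis genes in each library, with lines joining pairs. Interferon-stimulated genes start at 19.2 and 19.7 CPM in 2 controls and at 108 CPM in control sample 1, and macrophage markers stay under 1 CPM in both samples of pair 1.

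Genes of the hypoxia response and glycolysis were lower in all pairs. All 38 members were tested. In 31 of them all 3 pairs were lower, and in 0 all were higher. The pair medians were -0.29, -0.63 and -0.42. In the blocked DESeq2 fit 12 members fell, 0 rose and 26 did not pass. Adjusted over the list alone, 17 fell in that fit and 16 in blocked edgeR, against 0 in edgeR with the group alone. Members that fell include Hif1a, Pfkfb3, which makes an activator of glycolysis, at -0.78 ± 0.16 (SE), Eno2, an enolase, at -0.72 ± 0.17, and the glucose transporter Slc2a1 at -0.64. Stc1 and Vegfa also belong to this list. Pgk1, a glycolytic kinase, changed by -0.51 ± 0.16 and did not pass. The camera adjusted p was 1.1e-14, and 0.453 with an estimated correlation. With the block these were 1.5e-16 and 0.805.

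Markers of inflammatory CAFs, a state marked by cytokine secretion, had a median of -0.53 over 27 tested members, with pair medians of -0.22, -0.27 and -0.81. The list did not pass in camera with the group alone (adjusted p = 0.199) and passed with the block (adjusted p = 4.5e-04), but not with the block and an estimated correlation (adjusted p = 0.805). In the blocked DESeq2 fit 7 members fell and 1 rose, and adjusted over the list alone 12 fell and 2 rose. Has2, a hyaluronan synthase, fell by 1.14 ± 0.23 (SE) and Il1r1, the interleukin 1 receptor, by 0.84 ± 0.21 on the log2 scale, while Ccl8, a chemokine for monocytes, rose by 1.03 ± 0.25. Ly6c1 had a change of 2.12 ± 0.80 that did not pass. In edgeR with the group alone and without control sample 1, which breaks a pair, the list median was 1.08. Markers of myofibroblast CAFs, the contractile and matrix-producing state, had pair medians of 0.13, -0.11 and -0.03 over 28 members. Their median was positive (0.07) where the camera test pointed down (adjusted p = 0.959), and 0 members passed in the blocked DESeq2 fit.

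Among matrix proteases and their inhibitors, 41 of 43 were tested, with a median of -0.14 (camera adjusted p = 0.199). Mmp3, Mmp13 and Timp1 fell in the blocked DESeq2 fit and 0 rose. Mmp3, the stromelysin that activates other matrix proteases, fell by 1.85 ± 0.46 (SE), while Adamts12 (-0.72 ± 0.50), Adamts9 (-0.42 ± 0.17) and Ctsk (0.36 ± 0.15) did not pass. Of 39 collagens and crosslinking genes, 2 rose and 0 fell in that fit, with a median of -0.08 (camera adjusted p = 0.729). Col8a2, a short-chain collagen, rose by 1.85 ± 0.29 and Eln, elastin, by 1.23, whereas Col12a1 (-0.73 ± 0.69), Col8a1 (0.43 ± 0.16) and Lox (-0.32 ± 0.16) did not pass. Adjusted over the list alone, 3 proteases or inhibitors fell, and 3 collagens or crosslinking genes rose and 3 fell.

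Chemokines and cytokines moved both ways. Of 41 tested, 5 rose and 5 fell in the blocked DESeq2 fit, and 8 rose and 8 fell when adjusted over the list alone. Cxcl9 and Cxcl10, chemokines for T cells, rose by 6.82 ± 1.70 and 4.72 ± 1.41 (SE) and Il15, a cytokine for natural killer and T cells, by 1.66 ± 0.37. Il33, an alarmin, fell by 1.36 ± 0.27 on the log2 scale, and Cxcl1, a neutrophil chemokine, by 0.75. The list passed in camera as higher with the group alone (median 0.26, adjusted p = 0.034), but not with the block (adjusted p = 0.415) or an estimated correlation (adjusted p = 0.981). The call was also lost, and the median negative, without control sample 2 (-0.18, adjusted p = 0.552), control sample 3 (-0.0089, 0.292) or anti-Stat3 sample 1 (-0.24, 0.519), and it was lost without anti-Stat3 sample 2 (0.18, 0.058). Complement and acute phase genes likewise moved both ways, with 3 of 21 tested members higher and 5 lower in the blocked DESeq2 fit, and 5 higher and 9 lower when adjusted over the list alone (camera adjusted p = 0.729). The rises were in Serpina3f, Serpina3g and C4b and the falls included Lbp, at -1.49, and C3, at -0.84. C2 (1.54 ± 0.57) and Hp (-2.62 ± 0.99), a haemoglobin-binding plasma protein, did not pass.

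Cholesterol synthesis genes had a median of 0.35 over 24 tested members and were higher in all 3 pairs in 15 of them, with pair medians of 0.12, 0.41 and 0.36. No member passed in the blocked DESeq2 fit or when adjusted over the list alone, and the camera adjusted p of 0.047 (3.2e-07 with the block) was 0.981 with an estimated correlation. The call with the group alone was lost without control sample 1 (median 0.0040, adjusted p = 0.386), anti-Stat3 sample 2 (0.13, 0.858) or anti-Stat3 sample 3, where the median turned negative (-0.059, 0.849). Cell cycle genes stayed near 0, with a median of 0.02 over 42 members, pair medians of 0.02, 0.05 and 0.02, and 0 members past the threshold (camera adjusted p = 0.667).

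**Figure D4:**
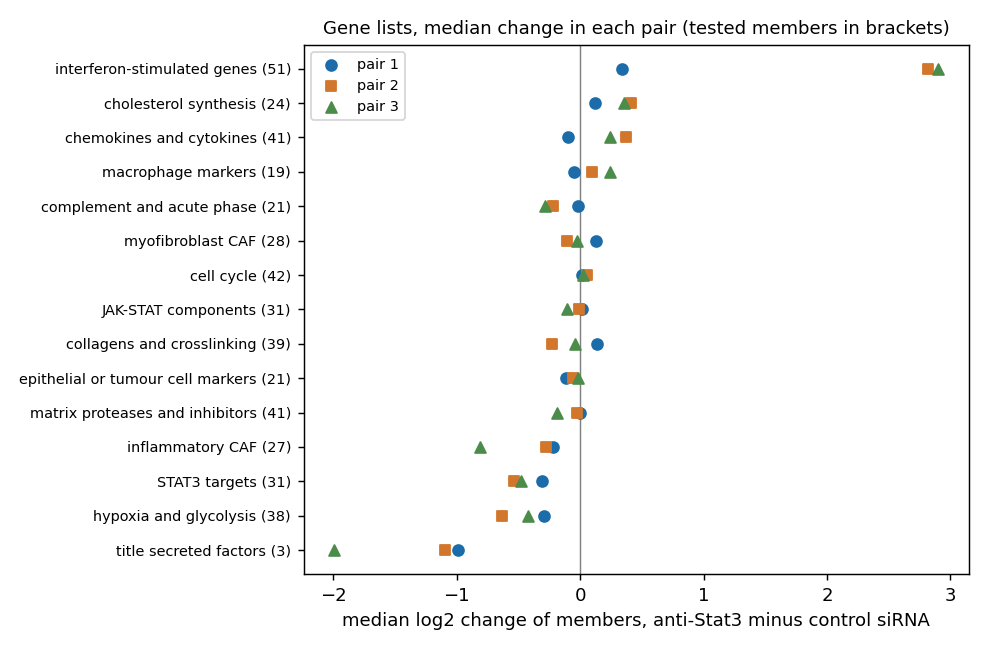
Median log2 change over the tested members of 15 gene lists in each of the 3 pairs, with the number of tested members in brackets. Interferon-stimulated genes stand at 0.34 in pair 1 and at 2.82 and 2.90 in pairs 2 and 3, and hypoxia and glycolysis genes lie below 0 in all pairs.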

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

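Blocked fits by DESeq2 and limma-voom, and blocked fits with other settings or without a pair, were chosen after the results were seen. With the group alone, edgeR called 0 genes under all scalings, filters, the batch term, a 1.5-fold test, a threshold of 0.01 and limma-voom, and DESeq2 called 17 (16 higher, 1 lower). With the replicate block, edgeR and limma-voom each called 8 (3 higher, 5 lower) and DESeq2 called 220 (116 higher, 104 lower). Leaving out each sample in turn gave 0 to 40 genes (0 to 40 higher), the 40 without control sample 1. Swapping labels within a pair, of which 4 ways exist, gave at most 0 genes in blocked edgeR against the real 8 and at most 1 in DESeq2 against 220, with 1 of the 4 ways reaching the real count in each. For the group alone all 10 splits of the samples reached the real count of 0, with 0 the highest other. Neither 4 nor 10 splits can give a share under 0.05. Leaving out each pair gave 0 to 703 genes in blocked edgeR (0 to 408 higher, 0 to 295 lower) and 14 to 432 in blocked DESeq2 (2 to 274 higher, 12 to 158 lower). The 703 genes without pair 1 include all 8 of the full set, and the 432 include 184 of the 220. Robust estimation gave 11 genes in blocked edgeR, 8 of them lower, and the other blocked settings 8 to 9 in edgeR and 218 in DESeq2. The cause was not tested for any of these changes. Stat3 passed at -2.33 in DESeq2 with the group alone, and with the block at -2.38 in edgeR, -2.38 in DESeq2 and -2.39 in limma-voom. With the block, DESeq2 also took Il6 (-1.18), Stc1 (-1.70) and Mmp13 (-1.72) past the threshold. In edgeR with the group alone and 1 sample left out, which breaks a pair, the Il6 change ranged from -4.10 to 1.78 and that of Serpinb2 from -7.68 to 2.14, both genes being high in pair 1. The pair changes of Serpinb2 were -2.65, -2.40 and -2.70.

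Of the 31 tested lists, 9 passed in camera, 5 with library totals alone, 5 without both samples of pair 3, 6 to 14 with 1 sample left out, and 0 with an estimated correlation or fry, with or without the block (0 in each). With an estimated correlation, camera rests on the few residual degrees of freedom of so few samples. A call lost there need not come from correlation between genes. The estimate was -0.018 for STAT3 targets (0.010 with the block), against the preset 0.01. It was 0.77 for interferon-stimulated genes (0.96 with the block) and 0.26 for hypoxia and glycolysis genes (0.22). STAT3 targets, interferon-stimulated genes and hypoxia and glycolysis genes passed in camera at the preset correlation under all scalings, filters and samples left out. Their medians still varied with the sample left out, from -0.43 to -0.27, 0.94 to 3.06 and -0.54 to -0.25 in that order. With 1 sample left out, these list medians changed sign: JAK-STAT components (-0.13 to 0.026), inflammatory CAF (-0.87 to 1.08), myofibroblast CAF (-0.087 to 0.21), collagens (-0.26 to 0.042), chemokines and cytokines (-0.24 to 1.23), cholesterol synthesis (-0.059 to 0.74), cell cycle (-0.13 to 0.21), complement and acute phase (-0.30 to 0.18), macrophage (-0.79 to 0.99) and epithelial markers (-1.38 to 1.26). Complement and acute phase genes also turned negative without the filter (-0.31), without both samples of pair 3 (-0.054) and with the block without pair 1 (-0.047), and myofibroblast CAF in the last (-0.080). Among list calls in camera at the preset correlation, the replicate block added inflammatory CAF and removed chemokines and cytokines, and it changed no other call. Of the 55 named genes' alternatives, 2 turned sign, 69 newly passed and 919 did neither. Over the 4 scalings the median of all genes in blocked edgeR lay between -0.012 and 0.020. In simulated data the group-alone edgeR test recovered few 2-fold changes, so its count of 0 does not bound changes of that size.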

Other observations

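The interferon test on macrophage content, the tests on the control level in pair 1 and on the siRNA itself, and the scaling test of the hypoxia genes were chosen after the results were seen; so were the label swaps of the blocked DESeq2 fit, as that fit was. The tests on GC content and length and the label swaps in edgeR were written before they were run, but after the calls and list medians they concern were seen.

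The control samples differed widely from each other, and whether culture, animal or handling lies behind this was not tested. Cxcl1, a neutrophil chemokine, stood at 1410 CPM in control sample 1 against 37.1 and 32.4 CPM in the other controls, Cxcl5 at 2561 against 200 and 152 CPM, and Ifit1, an interferon-induced antiviral gene, at 445 against 26.8 and 19.2 CPM. Ifnb1, interferon beta, had 1.96 and 1.75 CPM in the samples of pair 1 and 0 in the others, and Ifng had at most 0.067 CPM in any sample. Csn3, a milk casein, reached 412 and 438 CPM in pair 2 and at most 8.98 CPM in the other pairs. Col1a1, a main fibrillar collagen, had 7417 CPM in control sample 1 and 23429 and 22859 CPM in the other controls.

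Of the lists not described so far, those that passed in camera with the group alone were higher. Mitochondrial respiratory chain genes had a median of 0.15 (39 tested, adjusted p = 0.0012), p53 targets 0.19 (24 tested, 0.047) and apoptosis regulators 0.12 (28 tested, 0.034), and with an estimated correlation the adjusted p was 0.981, 0.981 and 0.737. In the blocked DESeq2 fit none of their members passed over all genes, and 5 apoptosis regulators rose when adjusted over the list alone. Growth and angiogenic factors (-0.02), NF-kB targets (0.00), immediate early genes (-0.10), TGF-beta targets (-0.06), the unfolded protein response (-0.02), oxidative stress (-0.22), antigen-presenting CAF markers (0.17), fibroblast identity genes (-0.08) and ribosomal protein genes (0.03) did not pass in camera, nor did markers of endothelial cells (0.26), pericytes and smooth muscle (0.08), adipocytes (-0.04) and myoblasts (0.11), all medians of the log2 change. Of 19 lymphocyte markers 2 were tested, too few for a list test. In a set of 13 genes of class I antigen presentation and processing, chosen after the values were seen, the pair medians were 0.48, 1.79 and 2.00.

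The rise of interferon-stimulated genes in pairs 2 and 3 has several candidate explanations. More macrophages in the anti-Stat3 libraries are argued against, since the 19 macrophage markers changed by a median of 0.14 in pairs 2 and 3 (SD over members 0.28) where the interferon list changed by 2.92, with no symbol in both lists. That bears only on a change in macrophage content within a pair. Both samples of pairs 2 and 3 held many macrophage transcripts. Whether fibroblasts or macrophages carried the rise cannot be told from these libraries and was not tested. A trend with GC content or transcript length is argued against too, since taking it out of the blocked changes left the list median at 2.04 from 2.10 (SD over members 0.81 in both). The small change in pair 1 may reflect a control level that was already high, but 49 of 51 members lay over 1.5-fold above the other controls there, and the 2 that did not changed by a median of 0.34 in pair 1 and 1.13 in pairs 2 and 3, so this cannot be told apart. A response to the sequence of this siRNA cannot be told apart from one to lower Stat3, because the design holds 1 anti-Stat3 and 1 control siRNA group; Stat3 fell by 2.66 on the log2 scale in pair 1, the pair with the smallest interferon change.

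The lower hypoxia and glycolysis genes were weighed against trends and scaling. Taking out the GC and length trend left the list median at -0.44 from -0.44 (SD over members 0.35 and 0.34), which argues against that trend as the whole cause. Over 4 scalings the list median nearest to 0 was -0.42, while the median of all genes lay between -0.012 and 0.020. A scaling factor moves all genes of a library alike. These values therefore argue against scaling as the source of the fall relative to the other genes. The scalings moved all genes too little to halve the change, so a shift common to all genes stays open. Culture density and oxygen are not given in the sources used here, and no biological explanation was tested.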
